A study of Mus musculus with 460 samples.

How the data were processed

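Single-cell RNA-seq was measured in 460 cells labelled as CAFs from mice with lung adenocarcinoma. Each sample in the series is 1 cell, and there is 1 group. The deposited table holds molecular barcode counts as whole numbers for 48440 genes in 460 cells, in a unit of counts. The submitters' processing notes name STAR, HTSeq and mm10, without versions or settings, and the labels describe the libraries as single-cell RNA-seq with sonication and ligation. The step that turned reads into barcode counts is not stated.

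The labels name no animal or culture, so the group was treated as 1 sample and no p-value, standard error or number of changed genes was computed from cells. Shares of cells carry exact Clopper-Pearson 95% intervals and summed counts exact Poisson 95% intervals, which cover counting error only. Cells with at least 1000 counts, 500 genes and at most 20% mitochondrial counts were kept, which kept all 460. Doublets were kept and no caller was run. An alternative left out the 5% of cells with the most counts. For comparisons across depths each cell was thinned to 56586 counts, the 10th percentile of totals, and 46 shallower cells were left out, leaving 414.

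CPM of a gene over the table is its summed count scaled to 1000000 summed counts, and cluster levels are means of the CPM of single cells. For 119 repeated symbols the gene with the most counts kept the symbol. Gene lengths came from GENCODE vM21, which matched 48058 of the gene identifiers without their version. Of 517 list entries 515 were measured, in 39 lists (15 marker lists and 24 programmes). Coherence is the mean pairwise Spearman correlation across cells, on log1p of counts scaled to 10000 per cell, between members detected in at least 10% of cells, with at least 3 members. It was set against 10000 random lists drawn from the same 20 expression bins, and a list is coherent above the 97.5th percentile. Relations between lists are Spearman correlations of mean z scores with shared genes removed, against 10000 random pairs, for 25 fixed pairs and 4 added later. A relation is called above percentile 97.5 or under 2.5.

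Variable genes were ranked by the log10 Fano factor of thinned counts over a lowess trend (span 0.3). Genes high in a minority of cells were those detected in 10 to 60% of thinned cells with a mean of at least 5 counts where detected. Clusters came from scanpy 1.11.5 with the Leiden method of igraph 0.11.9 (2000 variable genes, 20 principal components, 15 neighbours, resolution 0.5, seed 0, values scaled to at most 10, genes in at least 3 cells). Cluster genes are ranked by fold of mean CPM with 1 CPM added, among genes detected in at least 25% of the cluster. A cluster is called by a cell type only where at least 3 of its markers are detected in at least 25% of the cells and its score is highest there.

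The named genes are the 3 members of each list with the highest CPM, the closest pair of each coherent list, all fibroblast and CAF markers with Ptprc, Epcam, Pecam1, Cd44 and Zeb1, the 15 most abundant genes, the 20 most variable genes, 5 genes per cluster and the 10 most abundant genes high in a minority of cells. Ribosomal protein, mitochondrial and unnamed genes were left out of the last 4. A few genes that these rules select are not reported here, though list means and scores include them where they are members. The cell filter, lists, list pairs, settings, naming rules and first alternatives were fixed before the data were examined. Columns were called low in Sftpc where more than 50% of the 20 nearest columns had under 30 CPM of it. This split, the 4 added list pairs, the subsets of cells built on the split and on the smallest cluster, and a single-precision clustering were chosen after seeing the data. The exploratory single-precision run gave 5 clusters, and the double-precision run reported here gave 4.

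Fixed alternatives changed the cell filter, thinning, size factors (scran 1.30.0 in R 4.3.3), analytic Pearson residuals, the correlation, detection limits, cycling cells, the largest cluster alone, depth, cluster settings and count limits. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. The coherence and Fano steps were tested on simulated data of 13975 genes in 460 cells. Coherence planted with a log SD of 0.1, 0.2 or 0.4 was called in 7, 20 and 20 of 20 lists, and in 1, 0 and 0 of 20 lists without it. A dispersion raised 4-fold gave a median log10 excess of 0.257, where 0.263 was expected. At that strength 39 of 100 genes passed the excess limit of 0.3, and 3 of 100 at 2-fold, so the limit missed most simulated genes with such changes. All unchanged simulated genes shared a dispersion of 0.3. The measured genes had a median Fano factor of 3.44, so these shares need not hold for them.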

Results

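The 460 single cells labelled as cancer-associated fibroblasts (CAFs) of lung adenocarcinoma in mice carried a matrix-rich mesenchymal transcriptome. The 15 most abundant named transcripts included Fn1 (6200.1 CPM, counts scaled to 1000000 in all, for fibronectin), Bgn (4590.2; biglycan), Sparcl1 (3659), Igfbp7 (3318), Pdgfrb (2748; a receptor for platelet-derived growth factor), Sparc (2612), Col1a2 (2565), Col1a1 (2408), Col6a3 (2407) and Lrp1 (2314), together with Malat1 (5172), Rn18s-rs5 (4295), Actb (3186), Lars2 (2392) and Tmem176b (2371). The exact Poisson interval of Fn1 was 6176 to 6224 CPM. Ranks by CPM are not corrected for gene length. The labels name no animal or culture, so all cells count as 1 sample. No p-value is given, and every interval covers counting error only. The cells held a median of 88701 molecular barcode counts (quartiles 70338.5 and 111309) from a median of 7706 genes, with a median of 2.18% mitochondrial counts.

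Fibroblast markers were near universal. Of the 12 fibroblast genes, 10 had a count in at least 90% of cells, led by Fn1, Pdgfrb and Sparc. Col3a1 (1832 CPM), Pdgfra (1202), Dcn (891; decorin), Vim (867; vimentin) and Thy1 (362.5) were among them. Lum, which encodes lumican, was seen in 41.7% of cells (interval 37.2 to 46.4) and Fap, the fibroblast activation protein gene, in 3.04% (1.67 to 5.05; 1.17 CPM). Of the other genes fixed for naming, Cd44 had a count in every cell (467 CPM), while Zeb1 (68.03 CPM) had one in 76.5%. Ptprc, Epcam and Pecam1, markers of leukocytes, epithelium and endothelium, were counted in 11.3% (8.56 to 14.6), 5.43% (3.55 to 7.92) and 16.3% (13.05 to 20.003) of cells.

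Matrix genes varied together from cell to cell. Fibrillar and beaded collagens, led by Col1a2, Col1a1 and Col6a3, had a mean pairwise Spearman correlation of 0.270, above all of 10000 expression-matched random lists, with Col1a1 and Col1a2 at 0.857. The matrix glycoproteins and proteoglycans (Fn1, Bgn, Sparc; mean 0.188) and the basement membrane genes (Col4a1, 1923 CPM; Nid1, 1674; Col4a2, 1553; mean 0.139) also lay above all random lists. Their closest pairs were Mfap5 with Bgn (0.665) and Col4a1 with Col4a2 (0.909), the latter a neighbouring pair of type IV collagen genes. Collagen modifying and crosslinking genes (Loxl2 at 618 CPM, Pcolce at 535 and Serpinh1 at 363.4) reached a mean of 0.0597, percentile 99.96, with Lox and Loxl1 at 0.623. Matrix proteases and inhibitors (Timp3 at 1596 CPM, Timp2 at 1049.8 and Plat at 873) reached 0.0457, percentile 99.76, with Adamts2 and Timp2 at 0.446, a call that ended in the columns lacking Sftpc described below. The fibroblast list itself had a mean of 0.183, above all random lists.

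The myofibroblastic CAF genes were abundant and the inflammatory ones patchy. Postn (1654 CPM; periostin), Tnc (1055; tenascin C), Tpm1 (1002), Col12a1 (952), Acta2 (704; smooth muscle actin), Cnn2 (561) and Tagln (263.5) had a count in at least 90% of cells. Myl9 (101.5 CPM), Tpm2 (65.7), Mmp11 (36.96), Hopx (10.5), Itga11 (10.3), Cnn1 (7.86) and Lrrc15 (0.305) followed. Inflammatory CAF genes were led by C3 (257.7 CPM in 71.5% of cells; complement component 3), Lif (226.9 CPM, 76.3%) and the chemokine gene Cxcl12 (168.5 CPM, 75%). Behind them came Cxcl1 (131.04 CPM), Il6 (31.6 CPM, 25.7% of cells), Has2 (22.04), Ly6c1 (16.6), Has1 (15.4), Clec3b (13.8), Cxcl2 (13.6), Il33 (12.8), Saa3 (9.41), Ccl2 (4.65) and Ccl7 (1.103). Cxcl5 had no count, which limits it to 0.0866 CPM.

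Myofibroblastic and inflammatory scores did not oppose each other across cells. Their correlation was 0.109, at percentile 83.01 of random list pairs and so within the random range. Each list was coherent on its own: the myofibroblastic mean was 0.1498, above all random lists, with Acta2 and Tagln at 0.721, and the inflammatory mean 0.0525, percentile 99.77, with Lif and Cxcl12 at 0.253. Myofibroblastic scores rose with the TGF-beta response score (0.399, percentile 99.51). Inflammatory scores rose with collagens (0.269, percentile 99.67), TGF-beta response (0.266, percentile 99.63) and immediate early genes (0.210, percentile 98.44). Within cluster 1 alone, described below, inflammatory scores correlated with collagens at -0.106. That relation and the one with TGF-beta response returned to the random range there and also in the 72.4% of cells whose neighbouring columns have Sftpc. The relations with TGF-beta response (myofibroblastic), immediate early genes and hypoxia returned to the random range in 3, 4 and 3 alternatives. Collagens rose with matrix proteases and inhibitors (0.597, above all random pairs) and ran against hypoxia and glycolysis (-0.158, percentile 1.32). The other 19 of 25 fixed pairs lay within the random range, among them both CAF scores with the S and G2/M scores, interferon response with MHC class I (0.137), and collagens with the unfolded protein response (0.121).

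Clustering split the cells mainly along a mural axis. Cluster 1 (40.2% of cells, interval 35.7 to 44.9) is called pericyte-like. It had the highest score for pericyte or vascular smooth muscle markers. All 9 were detected in at least 25% of its cells, but so were 8 in each other cluster, so the name rests on levels. Mean Rgs5 was 5262 CPM there against 671, 430.96 and 195.02 CPM in clusters 2, 3 and 4, and Mcam (2035 CPM), Abcc9 (1536), Notch3 (1160.1) and Cspg4 (627) were likewise highest. Myh11 (28.2 CPM against 91.4 and 93.2 in clusters 2 and 3) and Des (458.05 against 639.9 in cluster 4), named after their values were seen, were not. Its leading genes were Gja4, Higd1b, Cxcr4, Adcy8 and Plxdc1. Pdgfra, a fibroblast receptor gene, was 403.4 CPM in cluster 1 and 1554 and 1939 CPM in clusters 2 and 3. These genes define the clusters and describe them only. The rule was also met there by antigen-presenting CAF genes, which are taken up below with the columns that lack Sftpc, and the choice between the names was made after the clusters were seen. Immune genes, which did not meet the rule, also summed highest in cluster 1 (450.01 CPM against 102.2, 98.2 and 208.5 in clusters 2, 3 and 4). The same held for endothelial genes (127.5 against 44.5, 18.4 and 30.7 CPM).

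**Figure D1:**
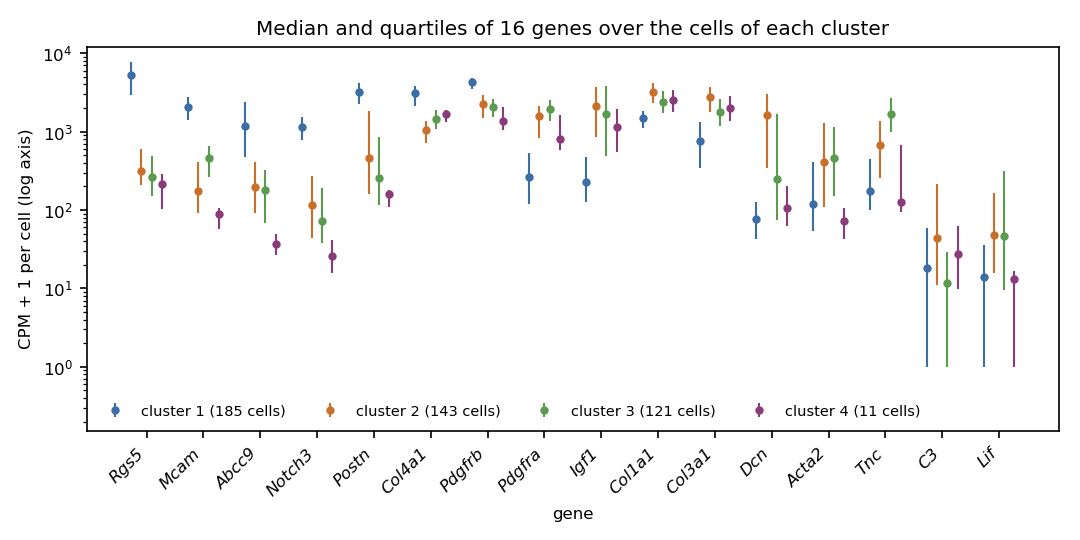
Level of 16 genes in the 4 clusters of the 460 cells. Points are medians over cells and bars span the quartiles, in CPM with 1 added, on a log axis, and mean Rgs5 is 5262 CPM in cluster 1 against 671 CPM in cluster 2.

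Rgs5 and Pdgfra ran against each other in single cells. Their correlation was -0.566, and Rgs5 exceeded Pdgfra in 91.4% of the cells of cluster 1 (interval 86.3 to 94.98) and in 20.98% (14.6 to 28.6), 2.48% (0.514 to 7.07) and 9.09% (0.230 to 41.3) of clusters 2, 3 and 4. Pericyte or vascular smooth muscle genes had a mean pairwise correlation of 0.392, above all random lists, led by Mcam with Notch3 at 0.753. In tests added after the clusters were seen, the pericyte score fell as the matrix glycoprotein (-0.609), collagen (-0.351), inflammatory (-0.324) and myofibroblastic (-0.224) scores rose, at percentiles 0, 0.04, 0.01 and 0.35. Acta2, although also a mural gene, ran against Rgs5 (-0.319). Within cluster 1 the pericyte and collagen scores correlated at 0.0504, and the relation with the myofibroblastic score also returned to the random range.

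Clusters 2 and 3 stay unnamed. Cluster 2 (31.1% of cells, interval 26.9 to 35.5) was led by Dpt, Mmp3, Itgbl1, Sv2c and C3 and met the naming rule for several fibroblast and CAF lists at once. Mean C3 was 720.3 CPM in it and 64.2, 29.6 and 74.2 CPM in clusters 1, 3 and 4, but the medians were 42.6 against 16.97, 10.6 and 26.3 CPM, so a minority of cells carried the mean. Mean Dcn was 1948 CPM against 125.2, 933 and 374.4. Cluster 3 (26.3% of cells, interval 22.3 to 30.6) was led by Moxd1, Mki67, Top2a, Plagl1 and Egfem1. It met the naming rule for cycling cells, with the highest G2/M (0.271) and S phase (0.206) scores. At thinned depth at least 5 G2/M genes were counted in only 17.5% of its cells, against 6.29%, 6.92% and 9.09% in clusters 1, 2 and 4. Mki67, a proliferation marker, was counted in 43.8% of the cells of cluster 3 and 46.9% of all others, and its mean was 148.3 against 19.02 CPM. In a test added later, the 10% of cells of cluster 3 with the most Mki67 held 91.8% of its level there. Median totals were 79456, 89241, 99997 and 82374 counts in clusters 1 to 4. The number of clusters depended on the settings, with 12 at resolution 1.0 and 7 with 1000 variable genes.

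The smallest cluster, 11 cells (2.39%, interval 1.20 to 4.24), carried posterior positional genes. It was led by Hand2, Hoxa10, A2m, Dio2 and Rorb. It met the naming rule for adventitial fibroblast, lipofibroblast and epithelial or lung tumour genes at once and stays unnamed. Epithelial genes summed to a mean of 2429 CPM in it against 1572.5, 914 and 666 CPM in clusters 1 to 3, a mean over unequal cells. Sftpc was 4865 and 2832 CPM in 2 of the 11 cells and 0 in 2, and its median outside the columns lacking it was 441.9 CPM, under the 465.5 CPM of cluster 1. Hox genes of paralog groups 9 to 13, which pattern the posterior body, summed to 1561 CPM in it and 3.57 CPM in the other cells, while groups 1 to 8 summed to 184.02 and 405.2 CPM. Hand2 (647 against 1.06 CPM), Hoxa10 (613 against 0.957), Hoxa11 (244.98 against 0.601) and the progesterone receptor gene Pgr (835 against 3.78) were counted in all 11 cells. Esr1, an oestrogen receptor gene, was 548 against 17.4 CPM. Tbx4 (30.01 against 543 CPM) and Tbx5 (39.96 against 690), transcription factor genes of lung mesenchyme, and Meox2 (4.93 against 132.6) were low. Tcf21 (57.3 against 26.005 CPM) was not, and Foxf1 stood at 116.3 against 185.6 CPM. As a background, Hand2 and Hoxa10 were counted in 4.23% and 6.24% of the other cells.

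**Figure D2:**
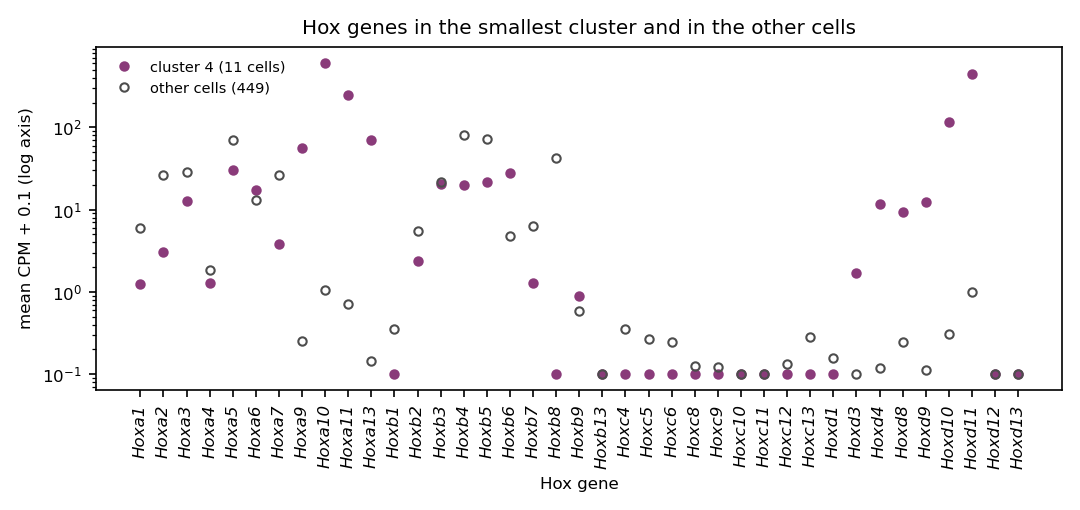
Mean CPM of each Hox gene, with 0.1 added, in the smallest cluster (filled, 11 cells) and in the other cells (open), on a log axis. Genes follow the order of clusters A to D and of paralog groups, and groups 9 to 13 sum to 1561 and 3.57 CPM.

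Transcripts of other lineages were widespread. At least 2 epithelial or lung tumour genes, led by the surfactant genes Sftpc (483 CPM), Sftpb (337.5) and Sftpa1 (151.96), were counted in 77.4% of cells (interval 73.3 to 81.1). For immune genes (Lyz2 at 178.7 CPM, Cd68 at 29.5 and Ptprc at 15.8) the share was 60% (55.4 to 64.5; 51.7% at thinned depth), and for endothelial genes (Vwf at 24.3 CPM, Kdr at 17.7 and Cdh5 at 12.5) 20.2% (16.6 to 24.2; 12.8% thinned). Lyz2, counted in 84.8% of cells, is also expressed by type II alveolar cells, so the immune share need not be leukocyte RNA alone. At least 2 mesothelial genes (Upk1b at 25.6 CPM, Upk3b at 13.6 and Msln at 9.11) were counted in 13.9% of cells. At least 2 erythroid genes were counted in 0 of 460 cells (upper limit 0.799%), although Alas2 reached 2.02 CPM, Hba-a2 0.117 and Hbb-bs 0.0704. Epithelial, immune and endothelial genes varied together, with mean correlations of 0.354, 0.144 and 0.152 above all random lists. Their closest pairs were Sftpc with Sftpb (0.874), Csf1r with Tyrobp (0.217) and Pecam1 with Cdh5 (0.227). The value for Sftpc with Sftpb pools the columns lacking Sftpc, described below (0.376 within them), with the others (0.735). The coherence of immune genes was -0.00270, and no longer called, without the cells richest in epithelial or immune counts, a selection on these same genes that favours the loss.

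Surfactant and antigen-presentation transcripts stopped together in 2 runs of columns. Antigen-presenting CAF genes were led by Cd74 (69.4 CPM in 60% of cells), H2-Ab1 (52.5, 43.5%) and H2-Aa (29.9, 35%), followed by H2-Eb1 (26.7), Slpi (10.3), H2-DMb1 (10.2) and their activator Ciita (3.47). The list had a mean correlation of 0.222, above all random lists, with H2-Ab1 and Cd74 at 0.513. In these runs, 27.6% of all cells, most neighbouring cells had under 30 CPM of Sftpc. At least 2 of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were counted in 3.94% of these cells (1.29 to 8.95) and in 71.5% of the others (66.3 to 76.3), or 2.83% and 62.7% at thinned depth. At least 2 epithelial genes were counted in 24.4% and 97.6%, a difference that the split favours, since it was made on Sftpc, a member of that list. Other lineages differed too, with at least 2 genes counted in 4.72% and 26.1% (endothelial), 1.57% and 18.6% (mesothelial) and 44.9% and 65.8% (immune). Immune genes without Lyz2 summed to medians of 20.6 and 20.4 CPM, so the typical cell did not differ in them, and to means of 110.5 and 73.2 CPM. Every cluster had cells in both sets, and median totals were 76488 and 92997 counts. The runs of columns were noticed in the data, and the labels give no batch.

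**Figure D3:**
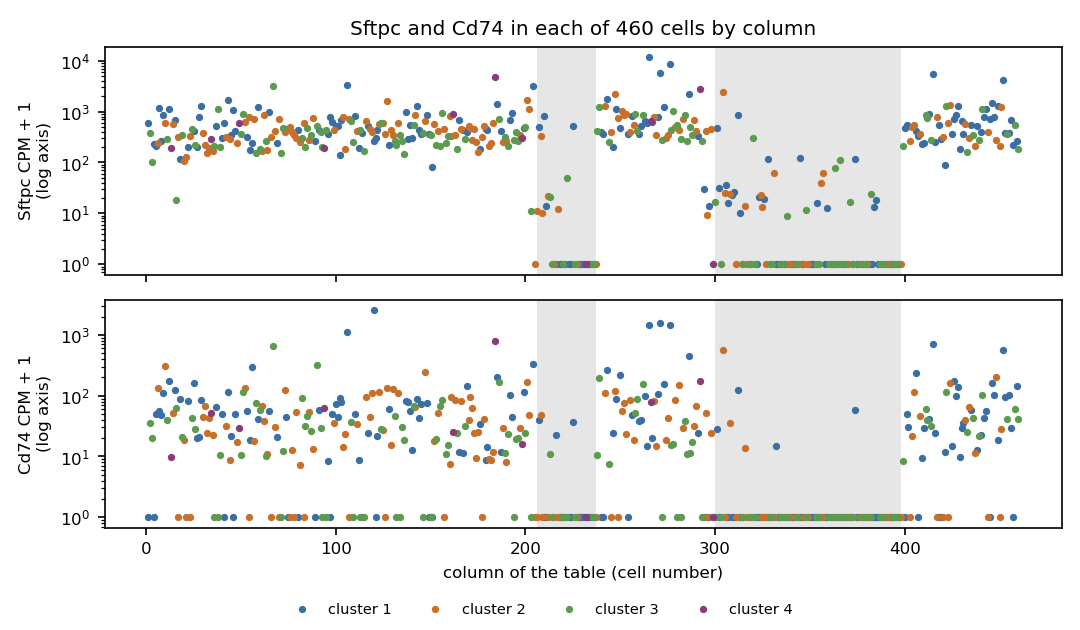
Sftpc (top) and Cd74 (bottom) in each cell, in the order of the columns of the table, in CPM with 1 added on a log axis. Grey areas mark columns whose neighbours lack Sftpc, where 3.94% of cells have at least 2 of 4 MHC class II genes against 71.5% elsewhere, and colours mark the clusters.

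Alveolar fibroblast genes (Macf1 at 1170.5 CPM, Limch1 at 249.5 and Npnt at 123.02) were coherent, with a mean of 0.145 above all random lists and Limch1 with Macf1 at 0.443, a call that ended within cluster 1. Adventitial (Col15a1 at 715 CPM, Col14a1 at 278.7 and Cd34 at 269.999), lipofibroblast (Lipa at 188.4, Plin2 at 115.8 and Lpl at 69.2) and peribronchial (Wnt5a at 438.5, Hhip at 133.8 and Aspn at 47.6) lists had means of 0.0333, 0.0474 and 0.0233. Their percentiles of 92.6, 89.9 and 75.5 lie within the random lists. The EMT and mesenchymal transcription factors (Zeb2 at 1374 CPM, Runx1 at 819.7 and Tbx4 at 522) also lay within them, with a mean of 0.0262 at percentile 88.5. In all, 32 of 36 summarised lists were coherent, and the mesothelial and erythroid lists were among those with too few members for a summary.

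**Figure D4:**
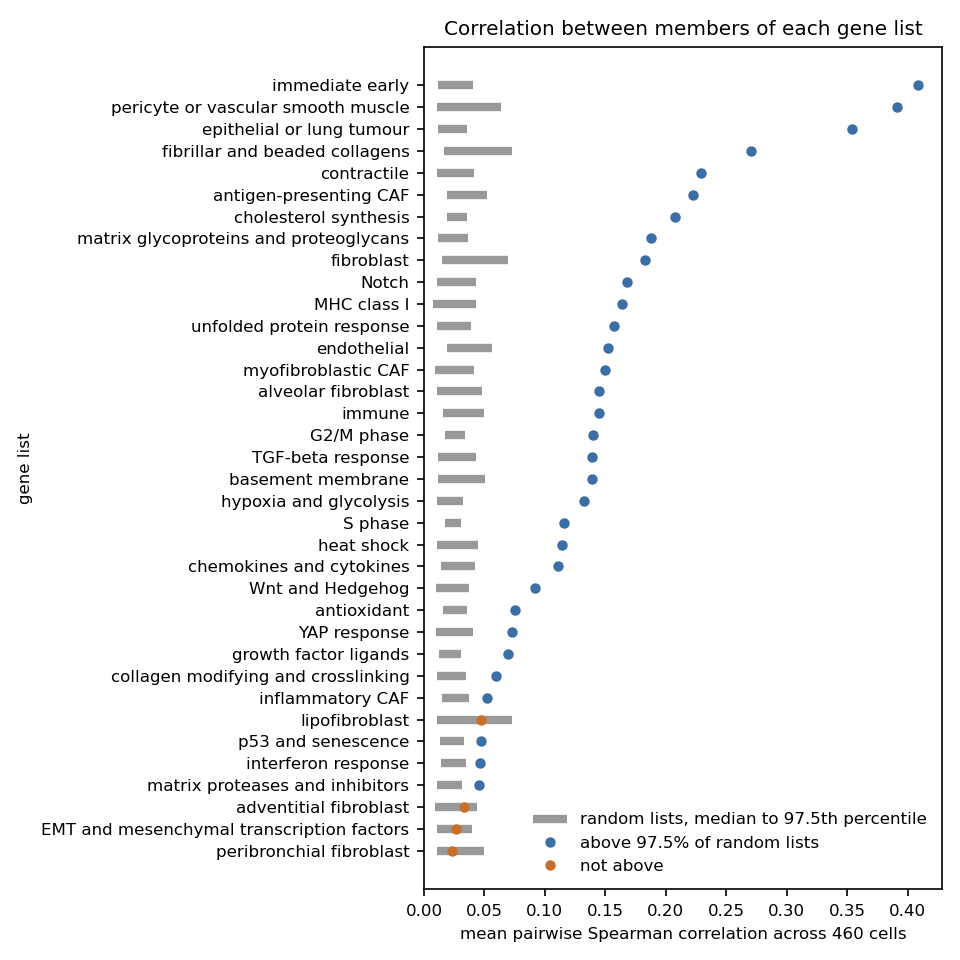
Mean pairwise Spearman correlation between the members of each of 36 gene lists across the 460 cells. Grey bars run from the median of 10000 expression-matched random lists to the limit for a coherent list, which 32 lists (blue) exceed and 4 (orange) do not.

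Signalling genes formed coherent groups, above all random lists except where a percentile is given. The Notch list (Notch3 at 506 CPM, Notch2 at 478 and Heyl at 334.98) had a mean of 0.168 with Notch3 and its target Heyl at 0.724. The Wnt and Hedgehog list (Tcf4 at 1080.2 CPM, Ptch1 at 978 and Dkk3 at 608) had a mean of 0.0915, percentile 99.99, with the Hedgehog targets Gli1 and Ptch1 at 0.634. TGF-beta response genes (Col1a1, Ltbp2 at 1105 CPM and Tgfbr2 at 745) had a mean of 0.139, with Ltbp2 and Col1a1 at 0.527, and YAP response genes (Cyr61 at 1330.2 CPM, Axl at 828 and Crim1 at 405.2) 0.0727, percentile 99.95, with Cyr61 and Amotl2 at 0.369. Growth factor ligands (Igf1 at 1606 CPM, Grem1 at 255.3 and Hbegf at 242.8) had a mean of 0.0694, with Igf1 and Bmp4 at 0.592. Chemokines and cytokines (Lif, Cxcl14 at 213.7 CPM and Cxcl12) had a mean of 0.111, with Cxcl12 and Cxcl14 at 0.408. Contractile genes (Flna at 1609.6 CPM, Myh9 at 1309 and Cald1 at 1259) had a mean of 0.229, with Acta2 and Tagln again the closest pair.

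Immediate early genes were the most tightly coupled list, and the stress and metabolic lists were coherent too, above all random lists except where a percentile is given. Nr4a1 (2162 CPM), Fos (2109.8) and Fosb (1790.3) led it, every pair was positive, and the mean was 0.408, with Junb and Nr4a1 at 0.773. This class is also known to respond to tissue dissociation. Heat shock genes (Hsp90ab1 at 2279 CPM, Hspa8 at 612 and Hsp90aa1 at 536) had a mean of 0.114, with the near-identical Hspa1a and Hspa1b at 0.868. The unfolded protein response (Hsp90b1 at 942 CPM, Calr at 840.2 and Hspa5 at 755) had a mean of 0.157, with Hsp90b1 and Calr at 0.487, and hypoxia and glycolysis (Gapdh at 522 CPM, Aldoa at 441.9 and Pkm at 344.4) 0.133, with Pkm and Aldoa at 0.537. Cholesterol synthesis genes, among them Hmgcs1 at 66.3 CPM and Fdft1 at 48.9, had a mean of 0.208, with all 91 pairs positive. MHC class I genes (H2-K1 at 421.5 CPM, B2m at 390.3 and H2-D1 at 346.7) had a mean of 0.164, with H2-K1 and H2-D1 at 0.602. Interferon response (Ifitm3 at 1093 CPM, Oasl2 at 135.8 and Irf1 at 116.5), p53 and senescence (Igfbp7, Igfbp5 at 578 CPM and Mdm2 at 131.8) and antioxidant genes (Prdx1 at 206.3 CPM, Gstm1 at 174.5 and Gclc at 68.5) had means of 0.0462, 0.0468 and 0.0755 at percentiles 99.78, 99.82 and 100. Their closest pairs were Oasl2 with Ifitm3 (0.256), Cdkn2a with Cdkn2b (0.274) and Mt1 with Mt2 (0.336). The interferon response lost its call in 5 alternatives, p53 and senescence within cluster 1 and in the columns lacking Sftpc, and antioxidant genes with Pearson residuals.

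Cell cycle transcripts were frequent but shallow. At least 3 G2/M genes were counted in 50.9% of cells (interval 46.2 to 55.5) and in 37.2% (32.5 to 42.1) at thinned depth, and at least 5 in 18.7% and 9.66%. At least 3 S phase genes were counted in 90.7% (87.6 to 93.2; 87.9% thinned). Mki67 (66.5 CPM), Hmgb2 (31.9) and Top2a (20.3) led the G2/M list, and Pcna (79.5 CPM), Rrm1 (46.1) and Slbp (45.9), the S phase list. The means were 0.140 for G2/M genes, with Mki67 and Ccnb2 at 0.252, and 0.116 for S phase genes, with Mcm5 and Mcm6 at 0.296, both above all random lists. The G2/M call ended with members in at least 25% of cells and within cluster 1, and both calls ended without cells holding 3 G2/M genes.

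Among genes counted in at least 10% of thinned cells, variation between cells ranked Hc, Chil3 and Spp1 highest, in an order that depended on the settings. Above the trend of the Fano factor (variance over mean) stood, in order, Hc, Chil3, Spp1, Mmp3, Dio2, Ibsp, C3, Apod, Lyz2, Slc34a2, Ccl6, Dlk1, Abi3bp, Ank, Ptgs2, Clu, Igfbp5, Lum, Gdf10 and Tmem119. Hc, which encodes complement C5, had a log10 excess of 1.80 with counts in 21.96% of cells, and the osteopontin gene Spp1 1.70 in 66.3%. Chil3, Lyz2 and Ccl6 are known macrophage genes, though type II alveolar cells also express Lyz2, and Slc34a2 is a type II alveolar gene. Of 12978 ranked genes, 11661 had a Fano factor of at least 2 and 1354 an excess of at least 0.3. Of 7817 genes counted in 10 to 60% of thinned cells, 5.05% had a mean of at least 5 counts where seen, a number that was 5.27 times larger with a mean of 3 counts asked for and 2.94 times larger with deposited counts. They were led by Spp1, Bmp3, Wif1, Hhip, Stc1, Cxcr4, Nrg1, Peg3, Ager and Chil3, with Bmp3 in 54.8% of thinned cells at a mean of 13.8 counts where seen.

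Some counts departed from independent draws at 1 rate in all cells. Genes counted in 5 to 10% of cells (2549 genes) had a median of 2.31 counts per detecting cell, where such draws give 1.04. Differences between cells and uncorrected barcodes would both raise it and were not separated, and the counting intervals cover neither. Across 13 mitochondrial protein genes the count rose with the length of the annotated gene (Spearman 0.934, a test chosen after seeing the counts). The count of mt-Co1 was 162.6 times that of mt-Co3. Yet mt-Nd6 (60.9 CPM) exceeded the longer mt-Co3 (22.4 CPM), and length was not separated from other differences between these genes. The 10 most counted genes rose with the cell total at a median log slope of 0.549, against 1.13 for 99 genes with a mean of 20 to 50 counts. Levels of short and of the most abundant transcripts should be compared between genes with care.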

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

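The shares of cells moved with depth and with the number of genes asked for, while coherence and relations mostly held. Without the shallowest 25% of cells, 64.6% had at least 2 immune genes, 94.5% at least 3 S phase genes, 59.1% at least 3 G2/M genes and 57.97% at least 2 of the 4 MHC class II genes, and the largest cluster held 35.4%. Thinned counts gave 51.7% (immune), 12.8% (endothelial), 37.2% (G2/M) and 47.3% (class II), and placed all 11 cells of the smallest cluster in a cluster of 20. Asking for 1 gene gave 86.96% (epithelial), 93.7% (immune) and 51.7% (endothelial), and for 3 genes 28.5% (immune) and 6.09% (endothelial). Asking for 2 or 5 genes gave 97.2% or 54.1% (S phase) and 75.2% or 18.7% (G2/M). In columns lacking Sftpc and in the others, chosen after seeing the data, the shares were 24.4% and 97.6% (epithelial), 44.9% and 65.8% (immune), 4.72% and 26.1% (endothelial), 82.7% and 93.7% (S phase), 35.4% and 56.8% (G2/M) and 3.94% and 71.5% (class II).

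There were 12 clusters at resolution 1.0 and 7 with 1000 variable genes. The largest cluster held 19.1% at resolution 1.0, 28.7% with 1000 variable genes, 29.3% with more variable genes, 28.7% with 10 principal components, 29.8% without cycle genes, 34.1% with Pearson residuals and 31.1% in single precision. In every setting at least 88.6% of the cells of cluster 1 fell in clusters of which they were the majority, though such clusters could hold other cells too. The 11 cells, of which 10 are left without the shallowest cells, stayed in 1 cluster. The number of genes high in a minority of cells was 2080 with a mean of at least 3 counts and 1160 with deposited counts, 5.27 and 2.94 times the number reported. Coherent lists numbered from 27 of 34 summarised (columns lacking Sftpc) to 35 of 36 (Pearson residuals). Of the 20 most variable genes, 8 stayed among the first 20 with genes in at least 5% of cells, 8 in columns lacking Sftpc, 11 with deposited counts and 13 or more in the other settings. Of the coherence values, 548 kept their call, 9 became coherent, 12 lost the call and 3 turned. The turned ones were G2/M at -0.105 without cells holding 3 G2/M genes (a selection that forces it), the coherence of p53 and senescence at 0.0103 within cluster 1, below the random median, and the coherence of immune genes at -0.00270 without the cells richest in epithelial or immune counts (a selection that favours it). Of the relations, 20 gained a call, 14 lost it and 2 turned within cluster 1: inflammatory with collagens (-0.106) and pericyte with collagens (0.0504). Myofibroblastic with inflammatory stayed within the random range throughout. Removing no cells by filter changed nothing, since all cells pass it.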

Other observations

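Matrix and signalling lists differed in level between the clusters, as a description of them. Basement membrane genes summed to a mean of 12945 CPM in the pericyte-like cluster and 8396, 8725 and 8693 CPM in clusters 2, 3 and 4. Notch genes, including the mural receptor gene Notch3, summed to 2910.4 against 1208, 1037 and 926 CPM. Fibrillar and beaded collagens went the other way, with 10567 CPM in cluster 1 and 18536, 13647 and 17165 CPM in the others. Postn stood at 3169.7 CPM in cluster 1 and 1161, 622 and 268.4 CPM in clusters 2, 3 and 4.

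The first pattern is the smallest cluster with posterior Hox genes, and its 3 tests were written before their results. Chosen after were the reading of Tbx4, Tbx5 and Meox2 alone and the setting aside of Hox genes in the uterine test. The demand that the lung gene ratio hold without any 1 gene was also chosen after. The test for doublets of lung fibroblasts with another cell type was written on both the total count and the lung gene ratio. Doublets are argued against by a median total of 0.926 times that of other cells (0.913 to 1.01 leaving out 1 cell). The median ratio of 6 lung genes, 0.246, was just under its bound of 0.25. Without 1 gene it ranged from 0.0579 to 0.434, so that part of the test cannot decide. Tbx4, Tbx5 and Meox2, at 0.0552, 0.0579 and 0.0372 of the other cells' level, go against doublets. Hoxa5, Foxf1 and Tcf21, the other lung genes tested, stood at 0.434, 0.627 and 2.20 and do not. Added epithelial RNA stays open for single cells, since Sftpc was 4865 and 2832 CPM in 2 of the 11 and 0 in 2. For cells of another organ, the median ratio of 6 lung genes was 0.246, just under its bound of 0.25, and without 1 gene it ranged from 0.0579 to 0.434, so this cannot be told apart from lung cells with another positional code. For uterine stromal cells, 6 of 7 listed genes were at least 5 times higher, but 2 of them are posterior Hox genes that restate the pattern and only 2 of the others were counted in 5 or more of the 11 cells, so they cannot be told apart from other posterior sources, which were not tested.

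The second pattern is the presence of epithelial and macrophage transcripts in most cells. Both tests were written before their results. The 10% of cells richest in epithelial genes held 49.5% of them, between the bounds of 30% and 50%, so free RNA in the suspension cannot be told apart here from other sources. That share pools the columns lacking Sftpc (median 12.5 CPM of these genes) with the others (879 CPM), and it was not computed within either. The 10% richest in immune genes, Lyz2 left out, held 72.9%, over the bound of 50% set for attached cells or doublets. The same share was 82.8% for endothelial, 81.2% for mesothelial, 69.6% for Schwann and 94.6% for erythroid genes. Lists with few counts thus pass this bound, so the test cannot tell attached cells or doublets apart from sparse counting.

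The third pattern is MHC class II transcripts in many cells (52.8% with at least 2 of 4 genes, 47.3% at thinned depth), and its tests and correlations were all chosen after seeing the result. Transcription by the fibroblasts themselves as a general source is argued against by the 3.94% of cells with 2 class II genes in columns lacking Sftpc. RNA from type II alveolar cells, which are known to express class II genes, could account for it, since summed levels in those columns were 0.0659 times those in the others. That test does not single them out, as cells with at least 2 endothelial (4.72% against 26.1%) or mesothelial genes (1.57% against 18.6%) were fewer there too. A difference in cell state between preparations stays open. Sftpc correlated with Cd74 within each set of columns (0.425 where Sftpc is lacking, 0.429 elsewhere), and more weakly with H2-Ab1 (0.184 and 0.288). These values cannot decide it, since the split used neighbouring columns and left cells with Sftpc among those lacking it. In the 2 runs, 25 of 30 and 83 of 97 cells were under 30 CPM. In all, 9 cells with at least 1000 CPM of the 4 genes hold 42.9% of the class II signal.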
